A study of Drosophila melanogaster with 12 samples.

How the data were processed

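Expression was measured in Kc cells, an embryonic Drosophila melanogaster line that responds to the steroid hormone 20-hydroxyecdysone (20HE). The 12 samples form 6 groups of 2 biological replicates. The groups cross RNAi against CP190, a chromatin protein found at insulators, or against beta-galactosidase as the control, with 0, 3 or 48 h of 20HE. Per the labels' protocols, total RNA was labelled with Cy3 and hybridised to NimbleGen arrays. Per the labels' design text, each array carries 8 probes for each of 16637 genes. The extraction protocol names a second cell line, Mbn2, while all 12 titles name Kc cells, and the samples were treated here as Kc.

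The authors deposited 1 table of intensity values on a linear scale, with 1 value per transcript and array. It had been processed with RMA per the submitters' processing notes; RMA corrects background, equalises the distributions of arrays and summarises the probes of a transcript. The RMA version, the annotation release and the genome build are not given in the sources used here. The table holds 16637 transcript identifiers and 1 random-sequence control, which was kept out of every test. Probe values were not used here, so the spread between probes of a transcript is unknown. No column or transcript duplicated another. Array medians lay between 1136 and 1227, and the random-sequence control between 413 and 425. Between 37.5 and 39.9% of transcripts lay within 1.5-fold of that control on an array, where background adds to the signal and makes fold changes too small, so a fold from or to such a level is given as a lower bound. The highest value of an array lay between 61018 and 65523, so the brightest transcripts sit near the end of the scanner's range.

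The log2 of each intensity was taken here, with no pseudocount, filter or further normalisation. Linear models of 6 group means over 12 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 6 residual degrees of freedom per transcript. P-values were two-sided and adjusted by Benjamini-Hochberg over 16637 transcripts within each comparison, with a threshold of 0.05. The comparisons were 3 h and 48 h of 20HE against 0 h in each RNAi arm, CP190 RNAi against control RNAi at each time and averaged over the 3 times, and the difference of the responses between the arms. Mean responses over both arms were used to choose responding transcripts. Errors of log2 changes are limma standard errors (SE), and errors of intensities are SD with n = 2. The number of arrays limits the precision.

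The labels give both replicates of every group the same pair of numbers. Across the 15 pairs of groups, the differences between replicate 1 and replicate 2 correlated across transcripts by 0.147 to 0.608, all above 0.1. By the rule set before the data were examined, the numbers therefore pair the samples, and counts from a model with the replicate number as a block are given where they moved by over 1.5-fold. The labels do not say what replicates of the same number share. The fit without the block was set as the main design before the data were examined, as were the comparisons, the alternatives and the rule for named genes, except where stated.

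Both fits were tested on simulated arrays in which 200 of 16637 transcripts were changed. Every transcript was given its estimated replicate difference, with noise of the spread found by the fit with the block. The advantage of that fit was therefore built into the simulation, which does not measure it on the real arrays. For 3 h against 0 h in control RNAi, the fit without the block recovered 38.5% of changes of 0.5 on the log2 scale, 98.0% of changes of 1 and 100% of changes of 2. For the difference of 3 h responses it recovered 0% of changes of 0.5, 93.5% of changes of 1 and 100% of changes of 2. The fit with the block recovered 95.5% of changes of 0.5 at 3 h and 37.5% for the difference of 3 h responses, with 7.73% and 7.41% of the calls false.

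Transcripts carry FlyBase identifiers, which the table does not pair with gene names. The RefSeq gene table of the Release 6 assembly GCF_000001215.4 listed 44 of these identifiers as synonyms. Of these, 16 belonged to 1 gene and were named, and 28 belonged to more than 1 gene and were not. The rule for named genes took, for 20HE in control cells and for the mean CP190 comparison, the 10 largest rises and 10 largest falls past the threshold whose replicates did not overlap, and 5 and 5 for the other comparisons. For differences of responses the threshold alone applied. Because these transcripts have no names here, at most 2 identifiers in each direction are printed per comparison. Cp190, EcR, usp, Eip74EF, Eip75B and br, which the rule also named, could not be looked up, so the depletion of CP190 RNA was not analysed here. Of 33 gene lists set in advance, 4 had 1 named member (alpha-Spec for cytoskeleton, LanA for matrix, kis for Polycomb and trithorax, His4r for histones) and the others had 0, so no list was tested. No coordinates are given, since the build behind the table is not given.

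Alternatives were the replicate block, quantile normalisation, centring each array on its median, leaving out the dimmest 30% of transcripts, limma with a trended robust prior, fits on only the arrays compared, a 2-fold minimum, and leaving out each array in turn. Intensity limits of 4-fold above the random control and 32768 were added after seeing the data, as were responders of at least 2-fold, the choice of responders on the other replicate, the split of the 0 h control arrays, the order of levels in both arms and the 48 h against 3 h contrast.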

Results

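Transcript levels were measured on 12 single-colour arrays of Kc cells, with 2 biological replicates in each of 6 groups. Cells received RNAi against CP190 or, as the control, against beta-galactosidase, and were collected after 0, 3 or 48 h of 20HE. Replicate arrays correlated across transcripts by 0.994 to 0.997, and the SD of the difference between replicates lay between 0.155 and 0.206 on the log2 scale. On all 12 arrays, 6569 of the 16637 transcripts were over 4-fold above the random-sequence control, and 5288 were within 1.5-fold of it.

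The early hormone response was read from control RNAi cells at 3 h against 0 h. FBtr0100515 went from an intensity of 646 ± 100.1 to 13270 ± 399 (SD, n = 2), a log2 change of 4.37 ± 0.12 (SE; at least 20.6-fold, limma adjusted p = 2.5e-09). Its replicate 1 at 0 h, at 576, lay within 1.5-fold of the random control. FBtr0088368 rose by 3.89 ± 0.099 (at least 14.9-fold, adjusted p = 1.32e-09), from 505 ± 4.53, within 1.5-fold of the random control, to 7510 ± 364, so the sizes of the 2 rises are not ranked. Fatp1, which encodes a fatty acid transport protein, rose by 1.33 ± 0.13 (2.51-fold, adjusted p = 2.85e-04), from 5405 ± 1180 to 13406 ± 640. FBtr0077877 fell by 1.21 ± 0.19 (adjusted p = 0.00603), from 5345 ± 328 to 2353 ± 614, and FBtr0113039 fell by 1.10 ± 0.20 (adjusted p = 0.0165). With the replicate block the adjusted p was 9.95e-06 and 3.45e-04. Neither passed with only the arrays compared (0.052 and 0.0947). FBtr0077877 did not pass without control 0 h replicate 1 (log2 change -1.14, adjusted p = 0.0629) or control 3 h replicate 2 (-0.94, 0.0563), nor FBtr0113039 without control 0 h replicate 1 (-1.17, 0.0711), control 0 h replicate 2 (-1.02, 0.116) or control 3 h replicate 1 (-0.80, 0.133). In all, 159 transcripts rose and 59 fell, 218 together or 1.31% of those tested, and 73 of them changed at least 2-fold. Of the 16 named genes, Fatp1 was past the threshold and 15 were not. With the replicate block the count was 386 (249 higher, 137 lower), and with only the arrays compared it was 89 (79 and 10). It was 142 without control 0 h replicate 1 (111 higher, 31 lower), 135 without control 3 h replicate 1 (98 and 37) and 146 without control 3 h replicate 2 (120 and 26).

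The late response, 48 h against 0 h in control RNAi cells, reached many more transcripts. FBtr0088368 rose by 6.02 ± 0.099 (at least 65.0-fold, adjusted p = 9.39e-12) to an intensity of 32849 ± 66.8, and FBtr0088367 by 5.99 ± 0.076 (at least 63.7-fold). Both began within 1.5-fold of the random control and ended above the upper intensity limit of 32768, so these measured folds are lower bounds. FBtr0082551 fell by 3.28 ± 0.16 and FBtr0079532 by 3.20 ± 0.14. The fall of FBtr0082551 is a lower bound, since its replicate 2 at 48 h, at 611, lay within 1.5-fold of the random control. NaPi-III, a phosphate cotransporter gene, fell by 1.14 ± 0.12 (adjusted p = 1.79e-05), from 9216 ± 1582 to 4143 ± 275, and sle, a nucleolar protein gene, fell by 0.62 ± 0.12 (adjusted p = 0.002). The gene mio, a component of the TORC1-regulating complex, rose by 0.26 ± 0.081 (adjusted p = 0.0321, and 0.0116 with the replicate block). That call was lost after centring each array (adjusted p = 0.111), with a trended robust prior (0.077), with only the arrays compared (0.0914), and without control 0 h replicate 1, control 0 h replicate 2 or control 48 h replicate 2 (adjusted p of 0.0759 to 0.21). Fatp1 was no longer past the threshold, with a log2 change of 0.28 ± 0.13 (adjusted p = 0.16; 0.0372 with the replicate block), and HDAC3, a histone deacetylase gene, had -0.26 (0.0976; 0.0128 with the block). In all, 2173 transcripts rose and 2543 fell, 4716 or 28.3% of those tested, and 851 changed at least 2-fold. The median change of all transcripts was -0.037 as deposited and -0.121 after centring each array on its median, which gave 1767 higher and 3894 lower. Without control 48 h replicate 1 there were 1725 higher and 1476 lower, without control 48 h replicate 2 1596 and 1639, and without control 0 h replicate 2 1732 and 1627, so the balance of rises and falls is not settled.

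**Figure D1:**
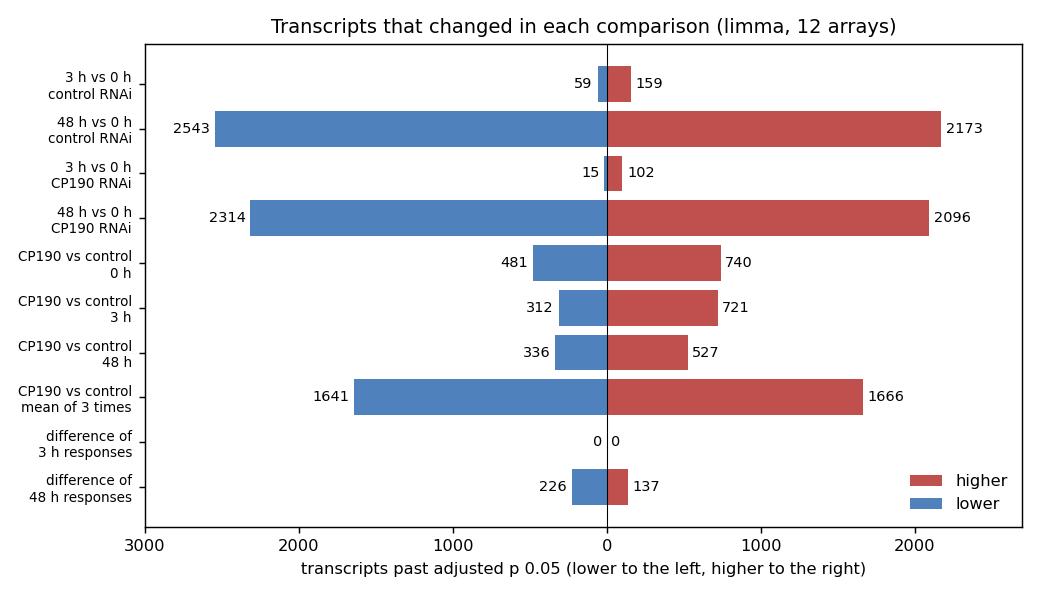
Bars give the number of transcripts past an adjusted p of 0.05 in each comparison (limma, 12 arrays), lower to the left and higher to the right of 0. The 48 h hormone comparisons hold 4716 and 4410 transcripts, against 218 and 117 at 3 h.

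Time courses differed among early transcripts. Of the 159 that rose at 3 h in control cells, 117 were also higher at 48 h, 5 were lower and 37 were not past the threshold. By the direct test of 48 h against 3 h, 67 rose further and 54 fell back. The 159 were chosen on the same 3 h arrays, which favours falling back. Fatp1 returned from 13406 ± 640 to 6483 ± 496 at 48 h, while FBtr0088368 went on from 7510 ± 364 to 32849 ± 66.8. Of the 59 that fell at 3 h, 35 were also lower at 48 h, 6 were higher and 18 were not past it. For changes averaged over both arms, 6465 transcripts were past the threshold at 48 h. Of these, 6219 (96.2%) were not past it at 3 h, 2696 of them higher and 3523 lower at 48 h. Only 1.91% of all transcripts tested were past it at 3 h, so a high share is foreseen for any list. The median size of the 48 h calls was 0.42. In control cells alone, a less precise test than the mean of both arms, 38.5% of simulated 3 h changes of 0.5 were recovered. Recovery for the mean of both arms was not simulated. With a high share foreseen for any list, the 96.2% does not show that these transcripts responded only late. The 3 h and 48 h changes in control cells share the 0 h arrays. Their correlation across transcripts, which are not independent, was 0.32 (rho 0.185) against 0.495 in simulated unchanged groups, and their covariance was 0.0309 against 0.00649. The lists shared 117 rises, against 20.8 for independent lists. The simulated groups shared 0, but being unchanged they hold no effects to share. With replicate 1 of the 0 h arrays as baseline for 3 h and replicate 2 for 48 h, the correlation was 0.0754 and the covariance 0.00908, with 72 shared rises against 14.1 for independent lists. With the baselines exchanged they were 0.299 and 0.0314, with 80 against 11.6. This split, added after seeing the data, leaves 1 array per baseline. With no array shared, 3 h in control cells and 48 h in CP190 cells had 112 shared rises against 20.0 for independent lists. Values for independent lists, here and below, treat all transcripts as equally likely to be called. Those near background were called less often, so unrelated lists would also share more than these values.

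CP190 RNAi cells also responded to the hormone. At 3 h, FBtr0100515 rose by 4.05 ± 0.12 and FBtr0088368 by 3.88 ± 0.099, both lower bounds from levels within 1.5-fold of the random control, and Fatp1 rose by 1.22 ± 0.13 (adjusted p = 7.53e-04). FBtr0077311 fell by 0.86 ± 0.12 and FBtr0079782 by 0.76 ± 0.10. The adjusted p of FBtr0077311 became 0.0557 without CP190 0 h replicate 2 and 0.0508 without CP190 3 h replicate 2, and that of FBtr0079782 became 0.0689 without the latter. In all, 102 rose and 15 fell, 41 of them at least 2-fold. The 3 h count of 117 became 229 with the replicate block (176 higher, 53 lower), 65 and 52 without CP190 0 h replicate 1 and 2, and 58 and 54 without CP190 3 h replicate 1 and 2. The 15 falls became 5, 2, 6 and 0 in these last 4 fits.

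At 48 h in CP190 RNAi cells, FBtr0088368 rose by 6.12 ± 0.099 and FBtr0088367 by 6.04 ± 0.076, again lower bounds. FBtr0084647 fell by 3.87 ± 0.19 and FBtr0082551 fell by 3.85 ± 0.16. NaPi-III fell by 0.99 ± 0.12 and sle by 0.71 ± 0.12, mio rose by 0.39 ± 0.081, and the histone gene His4r rose by 0.25 (adjusted p = 0.025), a call lost after centring each array (adjusted p = 0.0849), with only the arrays compared (0.0851) or without any of the CP190 0 h and 48 h arrays (adjusted p of 0.0705 to 0.122). The gene CG31178 fell by 0.32 (adjusted p = 0.0465) near background, a call lost after quantile normalisation (0.0638), with only the arrays compared (0.0811) or without any single array except CP190 0 h replicate 1 and control 3 h replicate 1 and 2 (adjusted p of 0.0522 to 0.345). With the replicate block the adjusted p was 0.0159 for His4r and 0.00769 for CG31178. Counts were 2096 higher and 2314 lower, 880 of them at least 2-fold, and centring each array gave 1744 higher and 3238 lower. Without CP190 0 h replicate 2 the count of 4410 became 2815 (1507 higher, 1308 lower), and without CP190 48 h replicate 1 it was 1587 higher and 1358 lower, so this balance is not settled either. Between the arms, which share no array, 3 h changes correlated across transcripts by 0.69 (Spearman's rho 0.279) and 48 h changes by 0.875 (rho 0.749). At 48 h, 1560 transcripts rose in both arms (273.8 for independent lists), 1660 fell in both (353.7) and 20 moved in opposite directions.

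**Figure D2:**
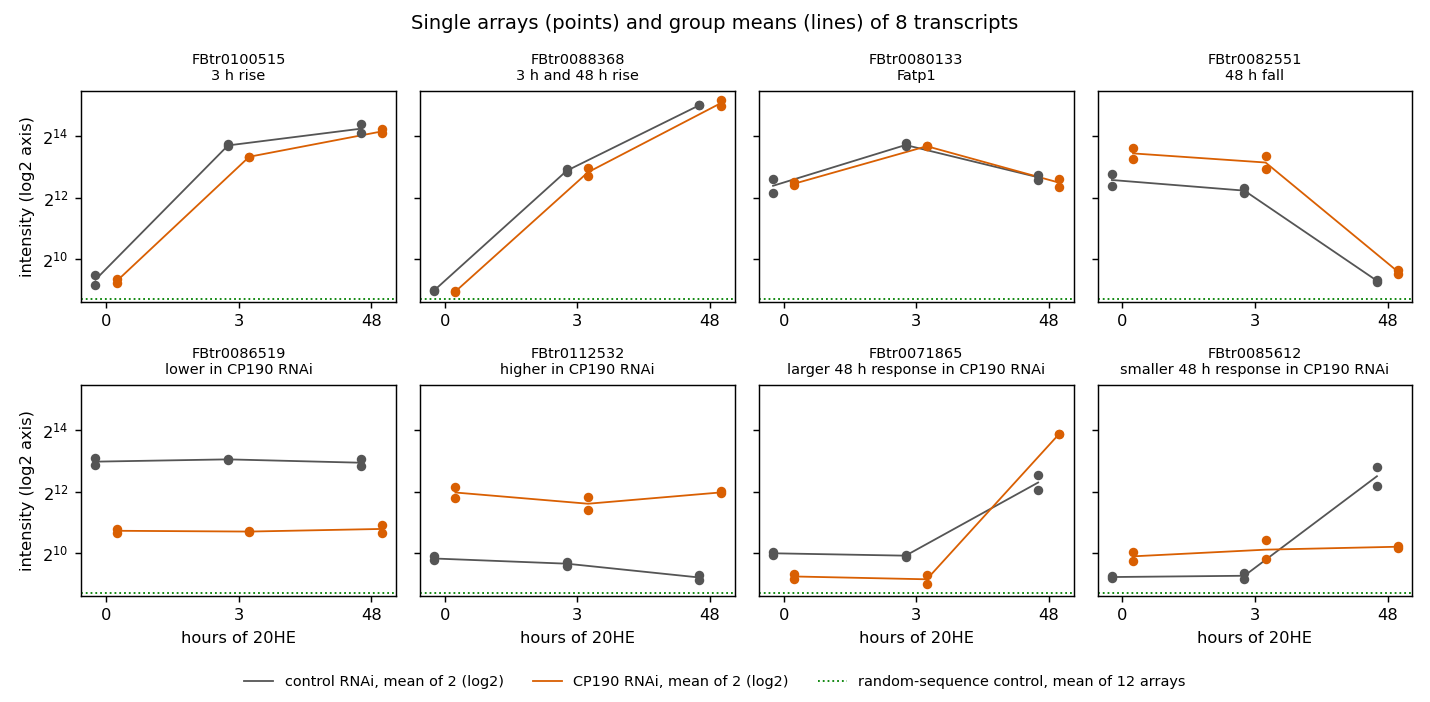
Intensity on a log2 axis against hours of 20HE (times evenly spaced) for 8 transcripts; points are single arrays, lines join the means of the log2 values of 2 replicates, and the dotted line is the random-sequence control. FBtr0086519 lies near 8081 in control cells and near 1696 in CP190 cells at 0 h, while FBtr0085612 reaches 5929 at 48 h in control cells and 1183 in CP190 cells.

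The effect of CP190 RNAi was read first as the mean over the 3 times. FBtr0112532 was higher by 2.29 ± 0.082 (4.88-fold, adjusted p = 1.51e-08), with intensities at 0 h of 908 ± 57.7 in control and 4043 ± 666 in CP190 cells, and FBtr0083324 by 2.04 ± 0.075. For both, control levels within 1.5-fold of the random control at some times make the size a lower bound. FBtr0086519 was lower, with a log2 change of -2.25 ± 0.066 (adjusted p = 9.58e-09), and FBtr0081747 with -1.84 ± 0.068, a bound on its size since it lay within 1.5-fold of the random control in CP190 cells. Among named genes, HDAC3 was lower (-0.23 ± 0.061, adjusted p = 0.0228) and mio was lower (-0.18 ± 0.046, adjusted p = 0.0188). The gene alpha-Spec, a membrane skeleton protein, was higher (0.18 ± 0.053, adjusted p = 0.0352). With the replicate block these adjusted p-values were 0.00102, 0.00479 and 0.0138. HDAC3 and mio were lower in replicate 1 than in replicate 2 in every group. Leaving out 1 array from the fit without the block therefore also unbalances the replicate numbers between the arms. The HDAC3 and mio calls were lost without CP190 replicate 1 of any time and without control replicate 2 of 3 or 48 h (adjusted p of 0.0518 to 0.0732), and that of HDAC3 also without control 0 h replicate 2 (0.0605). The alpha-Spec call was lost after centring each array (0.07), and without the same CP190 arrays, control replicate 2 of 3 or 48 h, or control replicate 1 of 0 or 48 h (adjusted p of 0.0613 to 0.102). With the replicate block rdx (0.17, adjusted p = 0.00893; 0.18 without the block) and CG31178 (0.16, adjusted p = 0.0229; 0.102 without it) were also past the threshold. FBtr0080239, chosen after its values were seen, was the only transcript near background in control cells at all 3 times (543, 521 and 509) and over 4-fold above the random control in CP190 cells (1957, 1989 and 2389). In all, 1666 transcripts were higher and 1641 lower, 19.9% of those tested, and 109 differed at least 2-fold. Centring each array gave 1403 higher and 2198 lower, the replicate block 2276 and 2633, and leaving out CP190 3 h replicate 1 or control 48 h replicate 2 gave 1300 and 1003 or 1330 and 1080, so the balance of directions is not settled.

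At single times, FBtr0083324 was higher by 2.85 ± 0.13 at 0 h (at least 7.23-fold, with control levels within 1.5-fold of the random control). It was higher by 2.61 at 3 h, also a lower bound, and FBtr0083371 was higher by 2.68 ± 0.26 and 2.51. FBtr0086519 was lower at both, with log2 changes of -2.25 ± 0.11 and -2.35. At 48 h, FBtr0112532 (2.77 ± 0.14, a lower bound) and FBtr0082725 (2.63 ± 0.19) had the largest rises by the naming rule, and FBtr0076243 (-3.24 ± 0.18) and FBtr0085612 (-2.29 ± 0.21) the largest falls. The gene CG31178, which lay near background, was higher at 3 h by 0.42 ± 0.11 (adjusted p = 0.0391), and was not past the threshold after quantile normalisation, with only the arrays compared, without any single array of CP190 3 h, CP190 48 h or control 48 h, or without control 3 h replicate 1 (adjusted p of 0.0511 to 0.214). The fit with the replicate block gave CG31178 an adjusted p of 0.00384 at 3 h. In that fit HDAC3 (-0.28, adjusted p = 0.0173, and 0.148 without the block) and mio (-0.26, adjusted p = 0.0246, and 0.0791 without it) were lower at 0 h. Counts were 740 higher and 481 lower at 0 h (672 and 638 after centring each array), 721 and 312 at 3 h (622 and 473 after centring), and 527 and 336 at 48 h. The totals of 1221, 1033 and 863 became 2614 (1330 higher, 1284 lower), 2091 (1223 and 868) and 1654 (900 and 754) with the replicate block. At least 2-fold changes numbered 189, 181 and 179. Fitting only the arrays compared gave 553 at 0 h (416 higher, 137 lower). Leaving out single arrays of the time compared moved the count at 0 h to 537 and 763 without CP190 replicate 1 and 2, 649 without control replicate 2 and, upwards, 1452 without control replicate 1, at 3 h to 460 and 661 without CP190 replicate 1 and 2 and 513 without control replicate 2, and at 48 h to 483 and 484 without control replicate 1 and 2 and 500 without CP190 replicate 1. The lower counts in these lists fell to 140, 207 and 182 at 0 h, to 97, 152 and 133 at 3 h, and to 210, 182 and 199 at 48 h, leaving aside control 0 h replicate 1 (694).

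The knockdown effects at 0 and 3 h, from different arrays, correlated across transcripts by 0.858 (rho 0.676), while those at 3 and 48 h correlated by 0.45 (rho 0.392) and those at 0 and 48 h by 0.466 (rho 0.445). At 0 and 3 h, 568 transcripts were higher at both (32.1 for independent lists) and 216 lower at both (9.02), with 0 in opposite directions. At 0 and 48 h, 203 were higher at both (23.4), 114 lower at both (9.71) and 10 in opposite directions.

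**Figure D3:**
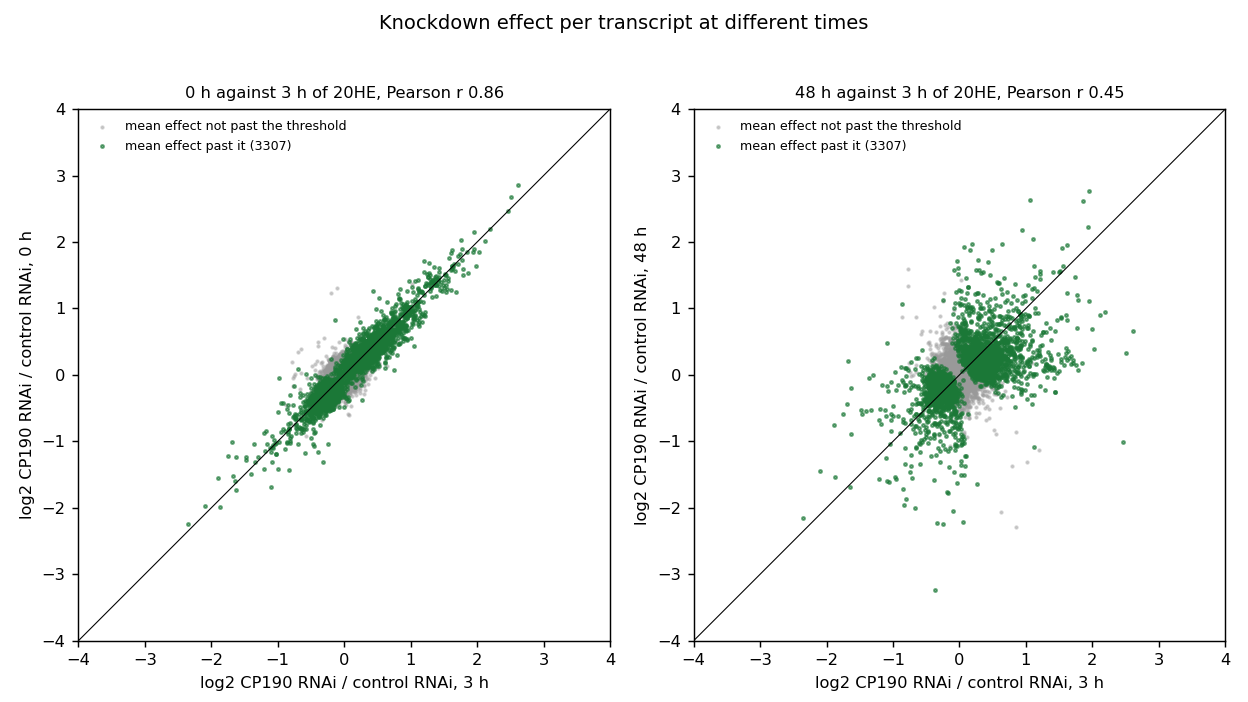
Log2 ratio of CP190 RNAi over control RNAi per transcript, at 3 h on the horizontal axis and at 0 h (left) or 48 h (right) on the vertical axis; green marks the 3307 transcripts past the threshold for the mean effect, and the line marks equal effects. Points lie closer to the line on the left (r = 0.858) than on the right (r = 0.45).

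The last question was whether the hormone response differs after CP190 RNAi, tested as the difference of responses. At 3 h, limma called 0 transcripts, with 403 at an unadjusted p under 0.05, 4 with the replicate block, all lower, and 1 without control 0 h replicate 2. Those 403, and 724 with the replicate block, are fewer than unchanged transcripts would give on average, so they are no sign of differences below the threshold. At 48 h, 137 responses were higher in CP190 cells and 226 lower, 363 together, of which 166 differed at least 2-fold. FBtr0071865 rose by 2.30 in control cells and by 4.64 in CP190 cells, a difference of 2.34 ± 0.21 (adjusted p = 2.04e-04), and FBtr0100135 by 0.83 and 2.93 (difference 2.09 ± 0.17). FBtr0084647 had a log2 change of -0.40 in control cells (adjusted p = 0.156; 0.0399 with the replicate block) and -3.87 in CP190 cells (difference -3.47 ± 0.27, adjusted p = 1.25e-04). FBtr0085612 rose by 3.28 in control cells and had a change of 0.31 in CP190 cells (adjusted p = 0.327; difference -2.97 ± 0.30, adjusted p = 4.39e-04). FBtr0071865 in CP190 cells and FBtr0085612 in control cells began within 1.5-fold of the random control, so those rises are lower bounds. None of the 16 named genes was past the threshold. The count was 725 with the replicate block (288 higher, 437 lower), 227 and 192 without control 48 h replicate 1 and 2, 196 without CP190 0 h replicate 1 and 239 without CP190 48 h replicate 2. The 137 higher responses became 71, 70, 66 and 98 in these 4 fits, and 81, 86 and 88 without CP190 48 h replicate 1, control 0 h replicate 2 and CP190 0 h replicate 2. It was 95 among transcripts within the intensity limits.

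Of the 363, the knockdown effect at 3 h ran opposite to the difference in 163, was not past the threshold in 181 and ran the same way in 19. In 137 the effect was opposite at 3 h and not past the threshold at 48 h, and in 160 it was not past it at 3 h and past it at 48 h. In 15 others the effect turned and was past the threshold at both times. FBtr0084647 was higher in CP190 cells at 3 h, with 15731 ± 3143 against 2854 ± 506 in control cells, and lower at 48 h, with 870 ± 64.9 against 1748 ± 238 (adjusted p = 0.00956).

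**Figure D4:**
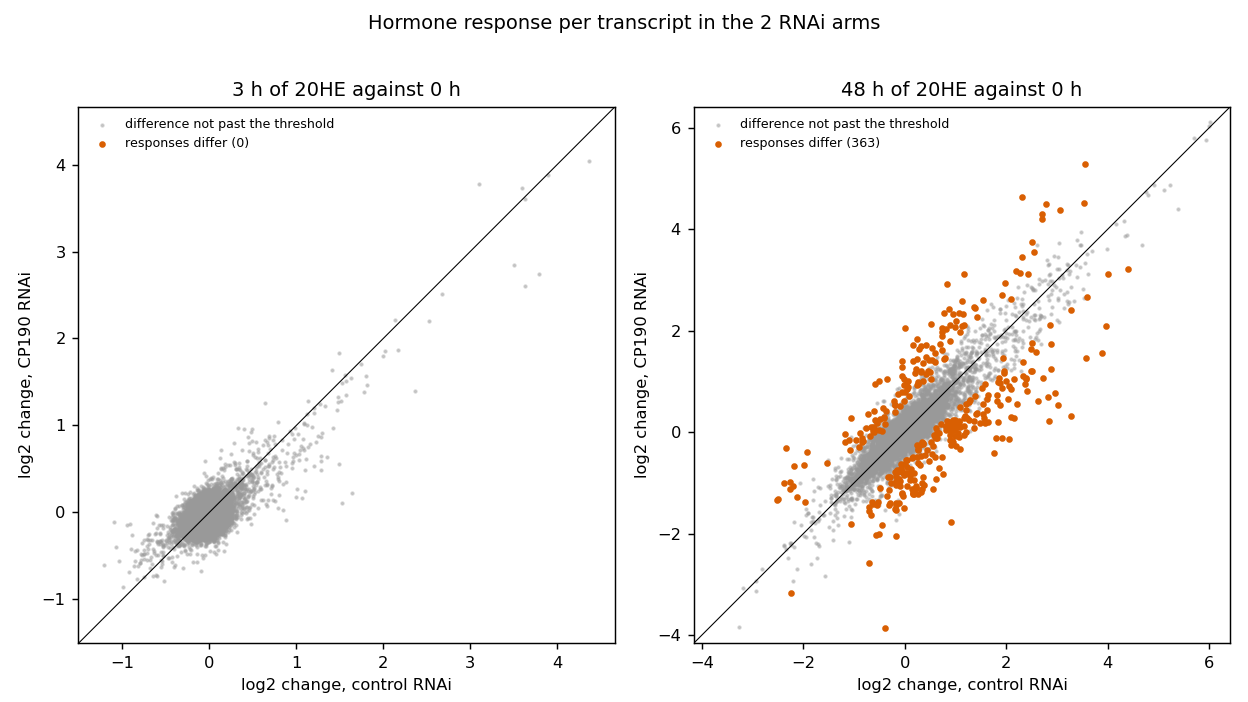
Log2 change from 0 h per transcript in control RNAi (horizontal) and CP190 RNAi (vertical) after 3 h (left) and 48 h (right) of 20HE, with a line of equal change. Orange marks transcripts whose responses differed, 0 at 3 h and 363 at 48 h.

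Over all 317 transcripts that responded at 3 h in the mean of both arms (591 with the replicate block), the median response was 0.66 in control cells and 0.51 in CP190 cells on the log2 scale, each taken in the direction of the response. The median difference was -0.13, and -0.14 and -0.10 in replicates 1 and 2. The response was smaller in CP190 cells for 241 of the 317 (76.0%), for 161 of 221 that rose and for 80 of 96 that fell. Taken in the direction of the response, the median knockdown effect of the 221 was 0.064 at 0 h and -0.042 at 3 h. For the 96 it was -0.199 and -0.299, so the arms already differed before the hormone. The 96 became 62, 57 and 62 without CP190 3 h replicate 1, CP190 3 h replicate 2 and control 3 h replicate 2. Adjusted over these transcripts alone, 7 differences passed, all among those that rose. The responders were chosen with the same estimate of spread, which favours transcripts with too low an estimate, so these adjusted p-values may be too small. Over the 6465 that responded at 48 h, the median difference was -0.012 and 52.2% were smaller. Its sign was not settled: it was 0.0415, 0.0047 and 0.0282 without CP190 0 h replicate 1, control 0 h replicate 2 and CP190 48 h replicate 2, and the mean was 0.00314 with responders chosen on the other replicate.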

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

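The tests of intensity limits and of the order of levels at 48 h and of a fading knockdown effect were chosen only after the result was seen. In 363 transcripts the 48 h hormone response differed between CP190 and control RNAi cells by the direct test of the difference. The examples are FBtr0071865 (difference 2.34), FBtr0100135 (2.09), FBtr0084647 (-3.47) and FBtr0085612 (-2.97). Compression at the ends of the intensity scale is argued against for part of them, since 95 passed when only transcripts within the limits were tested, and 254 of the 363 had a group mean outside them. Compression keeps the order of levels, and it is argued against for 93 of the 254, FBtr0071865, FBtr0084647 and FBtr0085612 among them, in which the larger response spanned the levels of the other on every array or the directions were opposite. For the other 161 the order of levels does not decide, and compression and a true difference in size cannot be told apart. A single array is argued against by a lowest count of 192 over the 12 fits that left out 1 array (control 48 h replicate 2; 196 without CP190 0 h replicate 1, 227 without control 48 h replicate 1, 239 without CP190 48 h replicate 2). This holds for the result as a whole. These fits were compared by count only, so a single array may still carry part of the 363. The knockdown effect grew between 3 and 48 h in 199 (54.8%), but the 363 were chosen on the same 48 h arrays. Of 363 transcripts chosen on replicate 1, 52.3% had a larger effect at 48 h than at 3 h on replicate 2. With the replicates exchanged it was 47.7%. Unchanged effects with noise would give similar shares, so these shares do not decide on a knockdown effect that only fades by 48 h. An effect that only fades keeps its earlier direction, opposite to the difference. In 100 of 137 higher and 94 of 226 lower differences, the effect at 48 h passed the threshold in the difference's direction. In 2 and 9 it passed the other way. Fading is argued against for the former as a set. Both lists use the 48 h arrays, so noise may have placed some there. They include the 15 whose effect was past the threshold in opposite directions at 3 and 48 h (10 of them among the 199). Fading stays open for the others, among them 151 of the 156 (43.0%) whose effect shrank, those that did not turn in this way. As a hypothesis, CP190 RNAi may alter the late response of some transcripts, while effects of the RNAi unrelated to CP190 stay open, since the depletion was not measured here.

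At 3 h, 7 transcripts had responses that differed between the arms when the adjustment was made over the 317 responders alone, while 0 passed over all transcripts. The choice of responders used the same estimate of spread as the test, so the 7 are not firm. The median response was smaller in CP190 cells by a signed difference of -0.13. Levels before the hormone enter into this difference, since the median signed knockdown effect of the 221 that rose was 0.064 at 0 h and -0.042 at 3 h. Unequal noise between the arms is argued against by responders chosen on 1 replicate number and measured on the other, a test added after seeing the data, where the mean of both medians was -0.115. No single array carried it, with a highest median of -0.11 over the 12 fits leaving out 1 array, and responders within the intensity limits gave a median of -0.135. A slightly weaker early response after CP190 RNAi is a hypothesis that these values leave open, as is a difference in hormone dose or timing between the arms, which was not tested.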

How the results depend on the processing

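The intensity limits, the 2-fold responders and the choice of responders on the other replicate were added after seeing the data. Quantile normalisation, leaving out the dimmest transcripts, centring and the trended robust prior kept the total of each comparison within 1.5-fold. Centring moved the balance of directions for 20HE at 48 h, for CP190 RNAi at 0 and 3 h and for the mean knockdown effect, and raised the lower counts by over 1.5-fold for 48 h in control cells (2543 to 3894), the mean 48 h response (3600 to 5604) and CP190 RNAi at 3 h (312 to 473). Of 1145 values of single named transcripts under alternatives, 1075 kept direction and threshold, 70 kept direction only and 0 reversed. These transcripts were chosen on the same arrays because they were past the threshold, most of them for large changes. Few reversals were therefore to be foreseen, and the shares do not hold for calls in general. The replicate block raised the counts for 20HE at 3 h to 386 (control) and 229 (CP190), for CP190 RNAi to 2614, 2091 and 1654 at 0, 3 and 48 h, for the differences of responses to 4 at 3 h and 725 at 48 h, and for the mean 3 h response to 591. It made the median signed 3 h difference -0.10 and moved no other total by over 1.5-fold. Among named genes it added the calls given in the report and SuUR in the mean 48 h response (adjusted p = 0.0351; 0.0574 without the block). Fits on only the arrays compared gave 89 for 3 h in control cells and 553 for CP190 RNAi at 0 h, and do not apply to comparisons using all groups. A 2-fold minimum left 73 and 851 (control, 3 and 48 h), 41 and 880 (CP190 cells), 189, 181, 179 and 109 (CP190 RNAi at 0, 3 and 48 h and mean), 166 (48 h difference), and 46 and 828 (mean responses), by its construction. Within the intensity limits the 48 h difference had 95 calls, with fewer transcripts tested. Responders chosen on replicate 1 and measured on replicate 2 gave a median 3 h difference of -0.0854. The median 48 h difference, -0.012, turned to 0.00307 and 0.00322 under choice on the other replicate, and to 0.0415 without CP190 0 h replicate 1, 0.0047 without control 0 h replicate 2 and 0.0282 without CP190 48 h replicate 2, so it has no settled sign. Apart from the 2-fold minimum and the limits, the cause was not tested.

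Leaving out 1 array at a time, with the lone array left assumed to vary like the other groups, gave 135 to 210 (3 h, control), 52 to 134 (3 h, CP190), 3201 to 4686 (48 h, control) and 2815 to 4663 (48 h, CP190). CP190 RNAi gave 537 to 1452, 460 to 1115 and 483 to 927 at 0, 3 and 48 h and 2303 to 3615 for the mean, and the mean responses 230 to 366 (3 h) and 5557 to 6386 (48 h). The differences gave 0 to 1 (3 h) and 192 to 343 (48 h), and the median differences -0.18 to -0.11 (3 h) and -0.080 to 0.0415 (48 h). The arrays that moved a total, or the higher or lower count of one, by over 1.5-fold are named beside the results in the report.

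The planned gene list tests, with preset or estimated correlation, the block, the dim filter and fry, were not run, since at most 1 member of a list had a name. Calls were fewer near background: of 6327 transcripts with a mean under 1.5-fold of the random control, 11.2% were past the threshold in the mean 48 h response, against 51.2% of those at 1.5- to 4-fold, 58.8% at 4- to 16-fold and 56.1% above. Changes hidden by low signal and transcripts that do not change cannot be told apart here.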

Other observations

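Transcripts that were near background at 0 h in both arms and over 4-fold above the random control at 48 h numbered 36, FBtr0088367 and FBtr0088368 among them, and 0 went the other way. Transcripts with consecutive identifiers moved together. Among 12790 such pairs, mean 48 h changes correlated by 0.286, by 0.721 in the 3838 pairs of close level and by 0.107 in the 3850 pairs of distant level. For the mean CP190 effect, 660 pairs were past the threshold in the same direction against 253 for independent calls. Consecutive identifiers can belong to 1 gene and share probe sequence, so counts of transcripts are not counts of genes.

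The overlap of the knockdown effect at 3 h with the 48 h hormone response, which share no array, was computed after the 48 h differences were seen. Of the 721 transcripts higher in CP190 cells at 3 h, 242 rose with 48 h of 20HE in control cells (94.2 for independent lists) and 168 fell (110.2). In CP190 cells 140 of them rose (90.8) and 311 fell (100.3). Of the 312 that were lower at 3 h, 92 rose in control cells (40.8) and 82 fell (47.7), while 117 rose in CP190 cells (39.3) and 45 fell (43.4). The mean knockdown effect was past the threshold for 5.01% of transcripts under 1.5-fold of the random control and 27.9 to 30.2% at higher levels. Unrelated lists would therefore also exceed the values for independent lists, and small excesses such as 168 against 110.2 are not read.

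For the mean CP190 effect, 100 splits of the arrays within times, the real one included, were compared. Only 1 of the 100, the real split, called as many transcripts (3307), and the highest of the others called 1034. The other splits mix the arms at some time or turn the sign of the knockdown effect at a time. A real effect then widens their spread or partly cancels, which lowers their counts. They therefore cannot exclude a chance split of the arrays as the source. Among the 30 splits that part all replicate pairs, the highest other was also 1034. Splitting replicate 1 from replicate 2 called 26.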
